A study of Arabidopsis thaliana with 36 samples.

How the data were processed

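Root sections of Arabidopsis thaliana Col-0 seedlings of CASP1::shy2-2/slr-1 and of its slr-1 background were sequenced. Per the labels, seedlings grew for 6 days on solid medium in continuous light, were moved to control plates or to plates with 10 µM NAA, and were 7 days old at harvest. The root tip (about 3 mm) and the shoot were removed. Stranded mRNA libraries were read as single reads. The 36 libraries form 12 groups of 3: each genotype untreated (0 h) and after 2, 4, 8, 16 and 24 h of NAA.

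The deposited files hold 1 count of reads per gene and library, made by the authors. Per the submitters' processing notes, cutadapt 1.3, STAR 2.4.0a and HTSeq 0.6.1 were used with the TAIR10 build, and no settings were given, so the use of strand in counting is unknown. Genes with near-identical copies (LHCB1.1 and LHCB1.3, GSTF6 and GSTF7, CYP71A12 and CYP71A13) are uncertain in such counts. Of the 32678 genes, 31912 were in the reference table used for symbols and coordinates, which is TAIR10.1. Coordinates were printed for identity only and not used with the counts. The 5 summary categories of each file (5.28 to 11.2% of reads, median 5.68%) were left out, and 6182 genes had no read. Reads in genes numbered 28.1 to 49 M per library, with 22023 to 22790 genes with a read, and the 10 most abundant genes took 6.43 to 8.38%. At this depth the spread between replicates exceeded counting noise, with a chi-square per degree of freedom of 3.98 to 118 for pairs of replicates, whose log2 CPM correlated at 0.9675 to 0.9949.

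Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling (factors 0.939 to 1.066), filterByExpr with the 12 groups (20939 genes tested, 11739 left out), and the robust quasi-likelihood F-test of a model with 1 mean per group (24 residual degrees of freedom, square root of the common dispersion 0.149). CPM are read counts scaled by library size and the TMM factor. The test was run for each time against the untreated controls of the genotype, for the genotype difference in that response (interaction), for the genotypes without NAA, and with 5 degrees of freedom over the times. Adjusted p-values are Benjamini-Hochberg within each comparison, called under 0.05, and every adjusted p of a gene in the texts is from this test. Principal components were taken of log2 CPM with a prior count of 2.

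Gene lists were 26 fixed lists from textbook knowledge with 336 loci, written before the data were examined, and the annotated GDSL esterase/lipase family (102 genes), which the study singled out. The lists were Aux/IAA repressors, auxin conjugation and oxidation, auxin perception and ARFs, auxin transport, lateral root initiation, overlying tissue separation, Casparian strip, suberin biosynthesis and export, suberin MYB factors, phenylpropanoid and lignin, cell cycle, expansins and xyloglucan enzymes, ethylene, cytokinin, abscisic acid, jasmonate and wounding, detoxification, iron uptake, circadian clock, and markers of root hair and epidermis, xylem, phloem, cortex, pericycle and stele, root tip and cap, and shoot and photosynthesis. For 12 listed symbols the reference table gives another name or none at the listed locus. Of these, 11 were kept by locus, and LTPG15 was dropped from the suberin list, since the reference names its locus LTPG5. Lists were tested with camera (limma 3.58.1, voom weights) at a correlation of 0.01 between genes, adjusted over the lists, and again with an estimated correlation.

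Named genes followed a rule fixed before the data were examined. It names IAA3, IAA14 and CASP1. For each genotype at 2 and 24 h, and for the untreated genotypes, it names the 5 largest rises and falls with an adjusted p under 0.05, a mean log2 CPM of at least 1 and the 3 libraries of a group all on one side of the other 3. It names the 20 genes with the smallest p in the 5-degree interaction test, and in each list up to 4 genes by p in slr-1 and 4 by p in the interaction. The text names fewer where calls were lost with 1 library left out.

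Replicate numbers were not taken as pairs: in 0 of the 11 comparisons did all numbered pairs correlate above 0.1. Library codes end in n (13 libraries), x (1, left out where the suffix was a term) or nothing (22), with unknown meaning. Simulated counts with 200 genes changed in single groups tested the pipeline. At 2 h and 1.5-, 2- and 4-fold it recovered 29.9, 92.5 and 100% in slr-1 (6 false calls) and 10.4, 64.2 and 100% in the interaction (8). Rates may differ in the data, with more calls. Alternatives were RLE size factors, DESeq2 1.42.0, no filter, a mean CPM of at least 5, a replicate block, suffix n as a term, libraries without a suffix alone, only the groups compared, thresholds of 0.01 and of log2 1, and each library left out. Total count scaling and leaving out slr-1 control replicate 3 and CASP1::shy2-2/slr-1 8 h replicate 3 together were chosen after seeing the data. For genes or libraries that could not be fitted under an alternative, no value was given.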

Results

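Transcripts were counted by RNA sequencing in root sections of 7-day-old Arabidopsis thaliana seedlings of 2 genotypes, with no treatment or after transfer to plates with 10 µM of the synthetic auxin 1-naphthaleneacetic acid (NAA). The slr-1 mutant carries a stabilised form of IAA14, a repressor of auxin-responsive transcription, and forms no lateral roots. CASP1::shy2-2/slr-1 carries in addition a stabilised form of the repressor IAA3 (SHY2) under the promoter of CASP1, a gene of the differentiated endodermis. Each genotype was sampled untreated and after 2, 4, 8, 16 and 24 h of NAA, with 3 libraries in each of the 12 groups and 36 in all. Reads counted in genes ran from 28.1 M (28105042) in CASP1::shy2-2/slr-1 at 2 h to 49 M in CASP1::shy2-2/slr-1 at 8 h, with a median of 39.3 M. In slr-1 the 3 libraries held 40.6 to 42 M reads in the controls, 33.1 to 36.4 at 2 h, 37.3 to 39.5 at 4 h, 32.5 to 45.7 at 8 h, 35.7 to 44.4 at 16 h and 38.4 to 46.2 at 24 h. CASP1::shy2-2/slr-1 libraries held 39.4 to 48.5 M in the controls, 28.1 to 34.7 at 2 h, 39.1 to 41.1 at 4 h, 32.7 to 49 at 8 h, 34.5 to 44.1 at 16 h and 37.8 to 42.4 at 24 h. Below, values after ± are standard errors for log2 fold changes and SD for normalised read counts (CPM), with n = 3 libraries per group in every case.

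The genes that the genotypes target came first. Without NAA, IAA3 (AT1G04240, a protein-coding gene on chromosome 1 at 1128149 to 1129689, minus strand, TAIR10.1) stood at 42.4, 38.4 and 39.3 CPM in the 3 slr-1 controls and at 38.6, 53.3 and 42.6 CPM in the 3 CASP1::shy2-2/slr-1 controls. This difference of 0.16 ± 0.12 did not pass the test (adjusted p = 0.351 by edgeR). In slr-1, IAA3 rose from 40.0 ± 2.11 CPM in the controls to 61.6 ± 2.45, 80.3 ± 5.33, 95.0 ± 19.4 and 82.5 ± 4.31 CPM at 2, 4, 8 and 16 h, and stood at 37.3 ± 2.11 CPM at 24 h. It stood in CASP1::shy2-2/slr-1 at 44.8 ± 7.61 CPM in the controls, at 52.6 ± 8.38, 45.2 ± 3.62 and 33.8 ± 4.62 CPM at 2, 4 and 8 h, and fell to 22.9 ± 1.06 and 23.9 ± 1.04 CPM at 16 and 24 h. The response differed between the genotypes by -1.65 ± 0.18 at 8 h and -2.01 ± 0.18 at 16 h on the log2 scale (adjusted p = 1.64e-06 and 1.3e-08 for the interaction). At 16 h IAA3 was lower in CASP1::shy2-2/slr-1 than in slr-1 by -1.85 ± 0.13 (adjusted p = 1.34e-11). Gene counts do not separate reads of the transgene from reads of the native gene, and neither stabilising mutation is visible in them, so these levels do not check the genotype labels.

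IAA14 (AT4G14550, protein coding, chromosome 4, 8347822 to 8350263, minus strand) rose in slr-1 from 5.69 ± 0.969 CPM to 28.2 ± 4.98, 16.9 ± 5.11, 21.5 ± 2.61, 17.3 ± 4.49 and 17.0 ± 4.30 CPM at the 5 times. It stood in CASP1::shy2-2/slr-1 at 6.75 ± 1.61 CPM in the controls, then at 5.96 ± 3.24, 5.13 ± 0.792, 7.95 ± 1.02 and 8.35 ± 1.61 CPM, and rose to 19.0 ± 4.81 CPM at 24 h. The response of IAA14 at 2 h was lower in CASP1::shy2-2/slr-1 by -2.49 ± 0.40 (adjusted p = 0.000438). CASP1 (AT2G36100, protein coding, chromosome 2, 15159591 to 15160799, minus strand), which marks the Casparian strip domain of endodermal cells, fell from 29.6 ± 24.4 CPM in the slr-1 controls to 4.09 ± 3.64, 0.932 ± 0.649, 1.89 ± 1.00 and 0.691 ± 0.170 CPM at 4, 8, 16 and 24 h. It stood at 26.1 ± 3.75 CPM at 2 h. It fell in CASP1::shy2-2/slr-1 from 53.3 ± 18.8 CPM to 11.1 ± 8.25, 3.52 ± 2.17, 5.03 ± 3.44 and 0.839 ± 0.136 CPM, with 47.4 ± 26.6 CPM at 2 h. The 5-df interaction test did not call CASP1 (adjusted p = 0.815), so CASP1 transcript was lower in both genotypes from 4 h on without a detected difference between them.

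**Figure D1:**
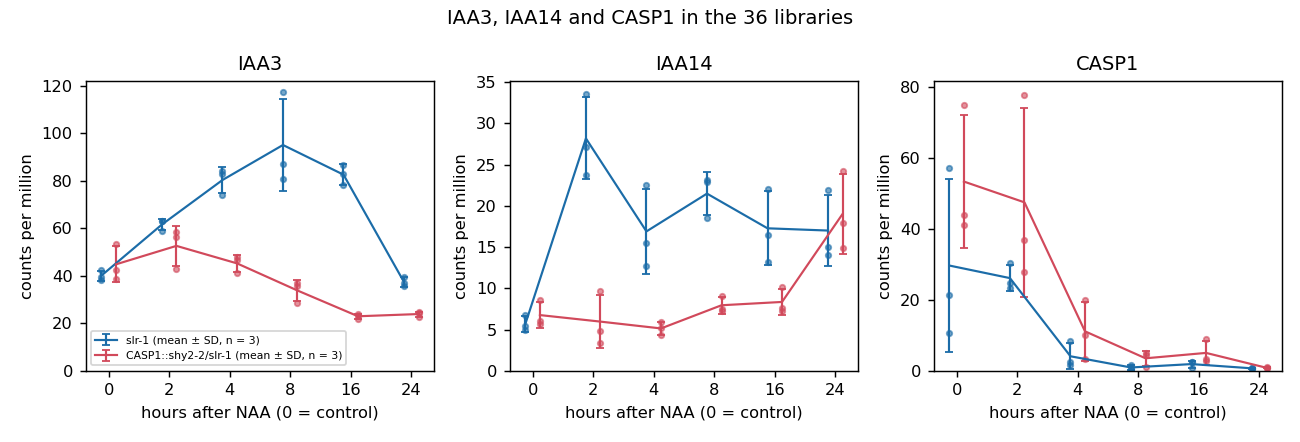
Normalised read counts (CPM) of IAA3, IAA14 and CASP1 in each of the 36 libraries against hours of NAA, with the mean ± SD of the 3 libraries per group for both genotypes. IAA3 rose in slr-1 to 117 CPM in replicate 3 at 8 h and fell in CASP1::shy2-2/slr-1 to 21.9 CPM in replicate 2 at 16 h, while CASP1 fell in both genotypes.

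Genotype and time of NAA structured the whole transcriptome. The first principal component of the log2 CPM values held 33.1% of the variance and ran from -82.2 in CASP1::shy2-2/slr-1 at 2 h to 79.5 in slr-1 at 24 h. The second held 14.5% and placed the CASP1::shy2-2/slr-1 controls at 40 to 42.9 and the slr-1 libraries at 4 h at -54.7 to -37.1. These libraries stood apart from their group. Replicate 2 of CASP1::shy2-2/slr-1 at 2 h, the 1 library with the suffix x, lay at -58.7 on the first component against -79.5 and -82.2, and at -22.3 on the third against 4.3 and 14.7. Its correlation of 0.9675 with replicate 3 was the lowest within a group. Replicate 3 of CASP1::shy2-2/slr-1 at 8 h lay at 8.9 on the second component against 42.5 and 42.2 for the other 2. Replicate 3 of the slr-1 controls lay at 15.9 against -1.5 and -2.0, and on the fourth component at -37.3. Replicate 3 at 16 h lay lower on the first component than its group in both genotypes, at 43.6 against 73.0 and 71.2 in slr-1 and at 8.2 against 54.4 and 47.8 in CASP1::shy2-2/slr-1. Both of these 16 h libraries have a code with the suffix n, whose meaning the labels do not give.

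**Figure D2:**
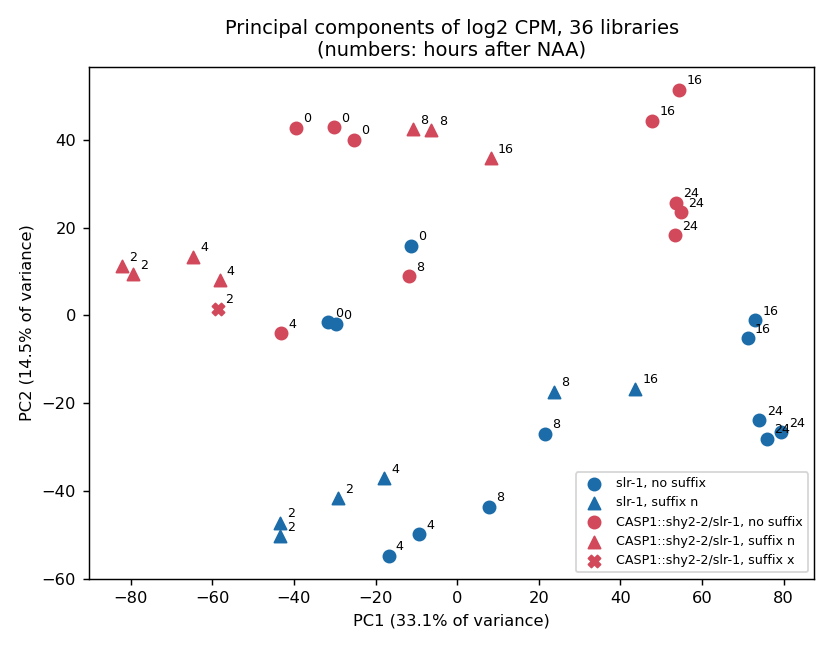
Scores of the 36 libraries on the first 2 principal components of log2 CPM (33.1% and 14.5% of the variance), with genotype and hours of NAA marked. On the first component the 24 h libraries lie at 74.1 to 79.5 in slr-1 and at 53.4 to 54.8 in CASP1::shy2-2/slr-1.

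The comparison of treated with untreated slr-1 roots asks which transcripts answer auxin where lateral root initiation is blocked. At 2 h GH3.2 and GH3.3, enzymes that conjugate auxin to amino acids, rose by 4.02 ± 0.18 and 4.06 ± 0.24 (log2), and LBD18 and LBD16, LBD transcription factors of lateral root initiation, by 2.60 ± 0.15 and 1.86 ± 0.16 (adjusted p at most 1.83e-09). Among genes with a mean log2 CPM of at least 1 and all 3 treated libraries on the same side of the 3 controls, the largest rises at 2 h were those of ELIP2 and ELIP1, early light-induced proteins (4.69 ± 0.58 and 4.61 ± 0.77). They were followed by the beta-glucosidase BGLU24 (4.59 ± 0.44), AT2G22590, annotated as a UDP-glycosyltransferase (4.52 ± 0.43), and the ABC transporter ABCG16 (4.50 ± 0.36). The largest falls were those of CYP71A12, a cytochrome P450 of indolic defence metabolism (-4.92 ± 0.73), the defence regulator ORA59 (-3.32 ± 0.43), AT5G22920, annotated as a zinc finger protein (-2.95 ± 0.81), AT1G33055 (-2.61 ± 0.67) and MEE14 (-2.61 ± 0.70). The adjusted p of these 10 genes was at most 0.00432, and reads of CYP71A12 may be shared with its near-identical neighbour CYP71A13.

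At 24 h MYB53, a MYB factor of the synthesis of suberin, the lipid polymer that seals endodermal walls, fell by 6.15 ± 0.31 (log2) and the acyltransferase gene GPAT5, which makes suberin monomers, fell by 4.04 ± 0.22 (adjusted p = 9.83e-15 and 6.15e-14). AT1G78990, annotated as an acyltransferase of the HXXXD type, had the largest fall (-7.82 ± 0.42), followed by the dirigent-like genes AT2G39430 (-6.78 ± 1.2), AT3G24020 (-6.72 ± 1.08) and AT3G55230 (-6.57 ± 0.91). The largest rises were those of AHP4, a histidine phosphotransmitter of the cytokinin pathway (5.70 ± 0.47), AT1G48325 (5.63 ± 0.67), the ethylene synthesis gene ACS8 (5.33 ± 0.59), SAG29, a SWEET sugar transporter (5.17 ± 0.43), and AT5G38100, annotated as a methyltransferase (5.16 ± 0.71). The adjusted p of these genes was at most 4.72e-05.

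Of the auxin lists, Aux/IAA repressors, conjugation, transport and lateral root initiation were called up in slr-1 at 2 h by camera, and these 4 calls were lost with an estimated correlation. Of the Aux/IAA repressors, themselves auxin-induced, 21 of the 27 measured members rose and 2 fell (21 and 2 adjusted over the list alone) at 2 h. The Aux/IAA median was 0.82, with adjusted p = 1.72e-08 by camera and adjusted p = 0.0534 with an estimated correlation. At 8 h 18 rose and 2 fell (18 and 2 adjusted over the list alone) (adjusted p = 4.15e-11 by camera, adjusted p = 0.03 with an estimated correlation). IAA19 rose by 3.68 ± 0.20 at 24 h, IAA30 and IAA11 by 3.65 ± 0.27 and 1.93 ± 0.14 at 8 h, and IAA29 by 4.58 ± 0.24 at 16 h. Of the genes of auxin conjugation and oxidation, 7 of the 10 measured members rose and 2 fell (7 and 2 adjusted over the list alone) at 2 h. The conjugation median was 1.39, with adjusted p = 0.000176 by camera and adjusted p = 0.0561 with an estimated correlation. The oxidase gene DAO2 fell by 1.44 ± 0.13 at 24 h, when the list stood at a median of 0.74 (adjusted p = 0.0175 by camera, adjusted p = 0.28 with an estimated correlation). Of the receptors and ARF transcription factors, 7 of the 17 measured members rose and 2 fell (7 and 3 adjusted over the list alone) at 2 h without a call for the list. The receptor and ARF median was 0.14, with adjusted p = 0.177 by camera and adjusted p = 0.573 with an estimated correlation. Rises included ARF4 (1.11 ± 0.14) and, at 8 h, ARF19 (0.93 ± 0.12). Of the auxin transport genes, 11 of the 19 measured members rose and 1 fell (11 and 1 adjusted over the list alone) at 2 h. The transport median was 0.62, with adjusted p = 5.22e-05 by camera and adjusted p = 0.0972 with an estimated correlation. Members called included the intracellular carrier gene PILS3 (1.85 ± 0.11) and the kinase gene PID (1.5 ± 0.24). At 24 h the transport list was called up. The transport median was 0.44, with adjusted p = 0.0455 by camera and adjusted p = 0.444 with an estimated correlation. Total count scaling ended this call, and PILS5 fell by 2.76 ± 0.24. Of the lateral root initiation genes, 10 of the 16 measured members rose and 0 fell (10 and 0 adjusted over the list alone) at 2 h. The lateral root median was 1.38, with adjusted p = 3.34e-05 by camera and adjusted p = 0.0991 with an estimated correlation. At 24 h 13 rose and 0 fell (14 and 0 adjusted over the list alone). The lateral root median was 2.21, with adjusted p = 3.27e-07 by camera and adjusted p = 0.0733 with an estimated correlation. Members called included LBD29 (2.81 ± 0.25 at 8 h) and LRP1 (2.31 ± 0.23 at 16 h). The overlying tissue separation list, genes of wall loosening and auxin influx in cells above a primordium, was not called at 2 or 24 h. At 2 h its mean was 0.10. The tissue separation median was -0.46, with adjusted p = 0.912 by camera and adjusted p = 0.946 with an estimated correlation. At 24 h its mean was -0.11. The tissue separation median was 0.30, with adjusted p = 0.71 by camera and adjusted p = 0.85 with an estimated correlation. In it the receptor gene HSL2 rose by 1.61 ± 0.17 at 2 h, while the polygalacturonase gene PGLR fell by 5.64 ± 0.71 at 24 h.

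In slr-1 camera called the suberin list up at 2 and 8 h and down at 24 h and the Casparian strip list down at 8 and 24 h. Of these 5 calls, that of the suberin list at 8 h alone passed with an estimated correlation. Of the suberin synthesis and export genes, 11 of the 14 measured members rose and 0 fell (11 and 0 adjusted over the list alone) at 2 h. The suberin median was 1.48, with adjusted p = 1.19e-07 by camera and adjusted p = 0.0561 with an estimated correlation. At 8 h 13 rose and 0 fell (13 and 0 adjusted over the list alone). The suberin median was 1.37, with adjusted p = 8.92e-11 by camera and adjusted p = 0.03 with an estimated correlation. At 24 h 4 rose and 8 fell (4 and 8 adjusted over the list alone). The suberin median was -1.40, with adjusted p = 0.0277 by camera and adjusted p = 0.444 with an estimated correlation. Falls included FAR5 (-2.55 ± 0.15), ASFT (-2.22 ± 0.20), ABCG6 (-3.43 ± 0.30) and the fatty acid hydroxylase gene CYP86A1 (-4.64 ± 0.30), while the reductase gene FAR4 rose by 1.63 ± 0.11. Of the suberin MYB factors, 5 of the 7 measured members rose and 0 fell (5 and 0 adjusted over the list alone) at 2 h. The suberin MYB median was 1.02, with adjusted p = 0.00143 by camera and adjusted p = 0.211 with an estimated correlation. At 24 h 0 rose and 7 fell (0 and 7 adjusted over the list alone). The suberin MYB median was -2.94, with adjusted p = 0.00017 by camera and adjusted p = 0.231 with an estimated correlation. Members called included MYB9 (-2.94 ± 0.29), MYB41 (-3.50 ± 0.50) and MYB92 (-2.35 ± 0.15). Of the Casparian strip genes, 3 of the 14 measured members rose and 3 fell (3 and 3 adjusted over the list alone) at 2 h without a call. The Casparian strip median was -0.49, with adjusted p = 0.897 by camera and adjusted p = 0.946 with an estimated correlation. At 8 h 0 rose and 9 fell (1 and 9 adjusted over the list alone). The Casparian strip median was -1.60, with adjusted p = 0.00792 by camera and adjusted p = 0.352 with an estimated correlation. At 24 h 0 rose and 11 fell (0 and 11 adjusted over the list alone). The Casparian strip median was -2.75, with adjusted p = 0.00125 by camera and adjusted p = 0.283 with an estimated correlation. SGN3, the receptor kinase of barrier surveillance, fell by 2.29 ± 0.21, the kinase gene SGN1 by 3.22 ± 0.31 and the dirigent gene ESB1 by 2.19 ± 0.31 at 24 h. Xylem markers fell at the same time: 0 of the 8 measured members rose and 7 fell (0 and 7 adjusted over the list alone) at 24 h. The xylem median was -1.87, with adjusted p = 3.27e-07 by camera and adjusted p = 0.042 with an estimated correlation. Members called included the protease genes XCP1 (-2.33 ± 0.14) and XCP2 (-2.28 ± 0.15) and the cellulose synthase genes IRX5 (-1.86 ± 0.15) and IRX1 (-1.75 ± 0.17). Of the phenylpropanoid and lignin genes, 14 of the 18 measured members rose and 1 fell (14 and 1 adjusted over the list alone) at 2 h. The phenylpropanoid median was 0.63, with adjusted p = 3.38e-06 by camera and adjusted p = 0.13 with an estimated correlation. At 24 h 1 rose and 11 fell (1 and 12 adjusted over the list alone). The phenylpropanoid median was -0.53, with adjusted p = 0.000267 by camera and adjusted p = 0.283 with an estimated correlation. PAL1 rose by 1.47 ± 0.19 at 2 h and the laccase genes LAC17 (-2.38 ± 0.13) and LAC4 (-1.99 ± 0.16) fell at 24 h. The GDSL esterase/lipase family, which the study singled out so that its count is no independent evidence, held 54 measured members, of which 11 rose and 13 fell (11 and 13 adjusted over the list alone) at 2 h and 9 rose and 26 fell (10 and 26 adjusted over the list alone) at 24 h. Its median was 0.08 with a mean of 0.26 at 2 h (adjusted p = 0.897 by camera, adjusted p = 0.946 with an estimated correlation) and -0.46 at 24 h (adjusted p = 0.0456 by camera, adjusted p = 0.28 with an estimated correlation), and the 24 h call was lost with no filter and with libraries without a suffix alone.

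**Figure D3:**
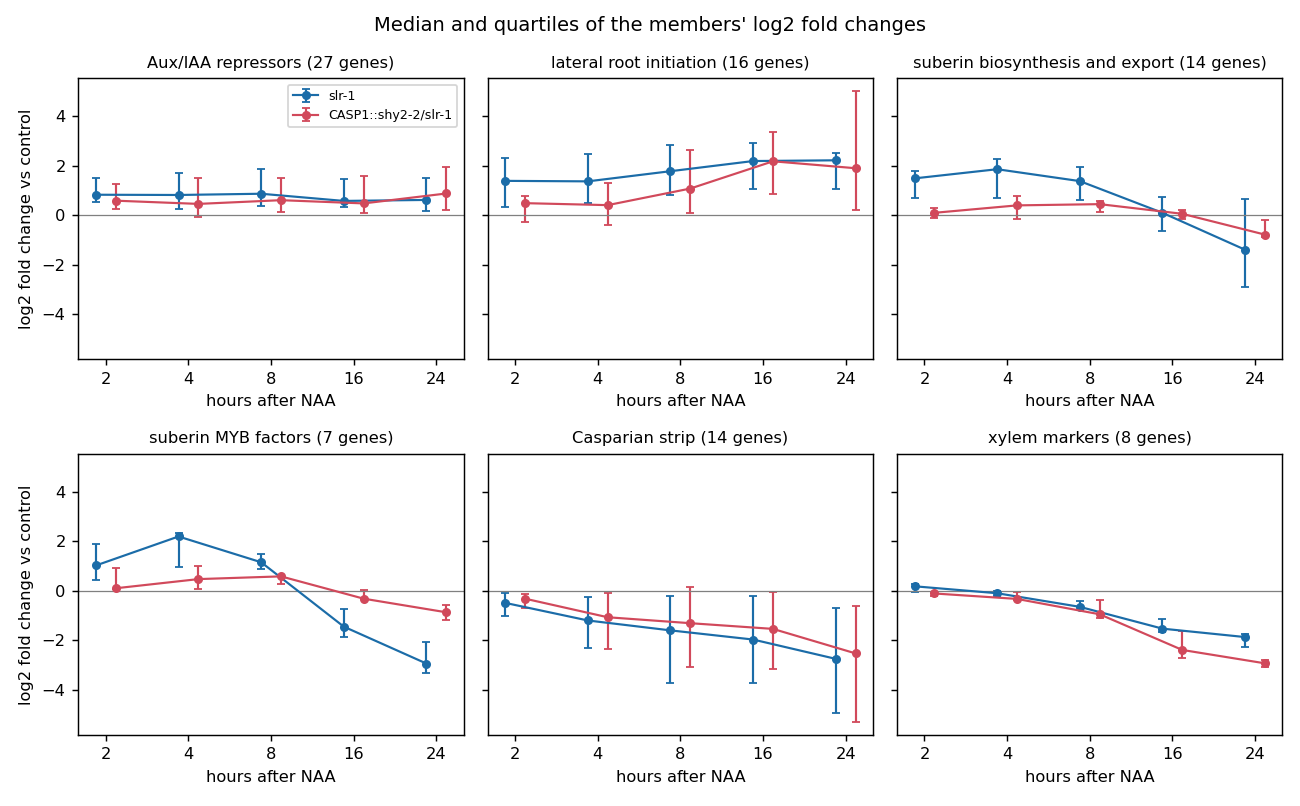
Median log2 fold change against the untreated controls of the same genotype, with quartiles over the members, of 6 gene lists (Aux/IAA repressors, lateral root initiation, suberin synthesis, suberin MYB factors, Casparian strip, xylem markers) against hours of NAA in both genotypes. The suberin median rose to 1.48 in slr-1 at 2 h and stood at 0.09 in CASP1::shy2-2/slr-1, and the xylem median fell to -1.87 and -2.93 at 24 h.

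In slr-1 camera called the ethylene list up and the cell cycle list down at 2 and 24 h, and the ethylene calls alone passed with an estimated correlation. The cell cycle median stood at -0.01 at 8 h and -0.11 at 16 h. Of the genes of ethylene synthesis and response, 9 of the 16 measured members rose and 0 fell (9 and 0 adjusted over the list alone) at 2 h. The ethylene median was 0.53, with adjusted p = 0.000221 by camera and adjusted p = 0.0232 with an estimated correlation. At 24 h 10 rose and 2 fell (10 and 2 adjusted over the list alone). The ethylene median was 0.92, with adjusted p = 0.00159 by camera and adjusted p = 0.042 with an estimated correlation. Members called included the receptor genes ETR2 (2.45 ± 0.16) and ERS1 (0.65 ± 0.08) and the F-box gene EBF2 (1.02 ± 0.10 at 8 h). Of the cell cycle genes, 1 of the 33 measured members rose and 20 fell (1 and 22 adjusted over the list alone) at 2 h. The cell cycle median was -0.39, with adjusted p = 0.000221 by camera and adjusted p = 0.493 with an estimated correlation. At 24 h 0 rose and 18 fell (0 and 18 adjusted over the list alone). The cell cycle median was -0.48, with adjusted p = 0.000806 by camera and adjusted p = 0.471 with an estimated correlation. Members called included the mitotic genes CDKB2;1 (-0.88 ± 0.11 at 24 h) and CYCB1;2 (-0.78 ± 0.12). Of the cytokinin genes, 5 of the 17 measured members rose and 4 fell (5 and 4 adjusted over the list alone) at 2 h, with a mean of 0.20. The cytokinin median was -0.25, with adjusted p = 0.897 by camera and adjusted p = 0.946 with an estimated correlation. At 24 h 4 rose and 11 fell (4 and 11 adjusted over the list alone). The cytokinin median was -1.05, with adjusted p = 0.0327 by camera and adjusted p = 0.444 with an estimated correlation. The cytokinin oxidase gene CKX4 fell by 5.25 ± 0.26 and the response regulator gene ARR4 by 1.52 ± 0.13 at 24 h, while CKX1 rose by 2.46 ± 0.19 at 8 h and CKX5 by 1.71 ± 0.14 at 2 h. Of the expansins and xyloglucan enzymes, 2 of the 22 measured members rose and 9 fell (3 and 9 adjusted over the list alone) at 2 h without a call. The expansin median was -0.32, with adjusted p = 0.424 by camera and adjusted p = 0.924 with an estimated correlation. XTH24 rose by 1.36 ± 0.24 and EXPB3 fell by 1.1 ± 0.24.

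By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8964, 8807, 7487, 9398 and 10506 of the 20939 genes tested changed in slr-1 at 2, 4, 8, 16 and 24 h, and 17045 over the 5 times together. The genes that rose and fell numbered 4243 and 4721 at 2 h, 4250 and 4557 at 4 h, 3754 and 3733 at 8 h, 4693 and 4705 at 16 h, and 4886 and 5620 at 24 h. Scaled by total counts, the share that rose was 61.9% in place of 49.9% at 16 h and 59.6% in place of 46.5% at 24 h. Libraries without a suffix alone gave 10436, 7858, 11473 and 12179 genes at 4, 8, 16 and 24 h, and no value at 2 h, where every treated library has one. Without replicate 1 of the controls, 4878 genes were called at 8 h, and with only the groups compared 5242 at 16 h. Each genotype had 1 untreated group, and the labels do not say how long it had been on control plates, so the effect of NAA is not separated from that of the hours since transfer.

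The comparison of treated with untreated CASP1::shy2-2/slr-1 roots asks what auxin changes when auxin response is also repressed in the differentiated endodermis. At 2 h IAA19 rose by 2.79 ± 0.20, GH3.2 by 1.53 ± 0.17 and LBD18 by 0.71 ± 0.15 (adjusted p at most 0.000755), while GPAT5 stood at 0.15 ± 0.18 (adjusted p = 0.554). The largest rises were those of the patatin-like phospholipase gene PLA2A (5.58 ± 0.47) and AT5G52050, annotated as a MATE efflux carrier (5.04 ± 0.46). They were followed by the glutathione transferase gene GSTF6 (4.87 ± 0.55), whose reads may be shared with the near-identical GSTF7, SEN1_AT4G35770, a senescence- and darkness-induced gene (4.84 ± 1.24), and CYP71A12 (4.53 ± 0.63). Large falls included those of PGLR (-3.76 ± 0.63), the transporter gene UMAMIT36 (-3.69 ± 0.66) and AT2G48080, annotated as a 2-oxoglutarate-dependent oxygenase (-2.93 ± 0.54). The adjusted p of these 8 genes was at most 0.00396.

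At 24 h ACS8 (6.66 ± 0.65), the lateral root gene MAKR4 (6.04 ± 0.36), AHP4 (5.68 ± 0.45) and AT5G02760, annotated as a protein phosphatase 2C (5.20 ± 0.44), had the largest rises, and RTFL10, a gene of the ROTUNDIFOLIA-like peptides, went from 0.0538 ± 0.00650 to 3.35 ± 0.441 CPM. The largest falls were those of AT5G04120, annotated as a phosphoglycerate mutase (-8.86 ± 0.61), the dirigent-like genes AT3G55230 (-7.56 ± 0.94), AT2G39430 (-6.85 ± 1.12) and AT3G24020 (-6.60 ± 1.01), and AT3G05770 (-6.71 ± 0.56). The adjusted p was at most 2.91e-05 for these 10 genes.

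The auxin lists moved in this genotype as follows. Of the Aux/IAA repressors, 15 of the 27 measured members rose and 1 fell (17 and 4 adjusted over the list alone) at 2 h. The Aux/IAA median was 0.58, with adjusted p = 6.32e-06 by camera and adjusted p = 0.165 with an estimated correlation. At 24 h 17 rose and 3 fell (17 and 3 adjusted over the list alone). The Aux/IAA median was 0.87, with adjusted p = 1.22e-06 by camera and adjusted p = 0.144 with an estimated correlation. IAA29 stood at 2.92 ± 0.24 and IAA19 at 4.10 ± 0.20 at 24 h. Of the conjugation and oxidation genes, 4 of the 10 measured members rose and 2 fell (4 and 2 adjusted over the list alone) at 2 h. The conjugation median was 0.51, with adjusted p = 0.0916 by camera and adjusted p = 0.567 with an estimated correlation. At 24 h 4 rose and 2 fell (5 and 2 adjusted over the list alone). The conjugation median was 0.12, with adjusted p = 0.154 by camera and adjusted p = 0.51 with an estimated correlation. Of the receptors and ARFs, 1 of the 17 measured members rose and 7 fell (1 and 7 adjusted over the list alone) at 2 h. The receptor and ARF median was -0.18, with adjusted p = 0.0236 by camera and adjusted p = 0.491 with an estimated correlation. This call was lost with the suffix as a term. Falls included ARF6 (-0.73 ± 0.13) and ARF16 (-0.32 ± 0.10). Of the auxin transport genes, 6 of the 19 measured members rose and 3 fell (6 and 3 adjusted over the list alone) at 2 h. The transport median was 0.08, with adjusted p = 0.406 by camera and adjusted p = 0.705 with an estimated correlation. Of the lateral root genes, 7 of the 16 measured members rose and 1 fell (7 and 3 adjusted over the list alone) at 2 h. The lateral root median was 0.48, with adjusted p = 0.255 by camera and adjusted p = 0.647 with an estimated correlation. At 24 h 11 rose and 0 fell (11 and 0 adjusted over the list alone). The lateral root median was 1.89, with adjusted p = 2.11e-05 by camera and adjusted p = 0.144 with an estimated correlation. LBD29 rose by 4.78 ± 0.33 and LBD16 by 3.08 ± 0.18. Of the tissue separation genes, 0 of the 9 measured members rose and 3 fell (0 and 3 adjusted over the list alone) at 2 h. The tissue separation median was -0.70, with adjusted p = 0.108 by camera and adjusted p = 0.611 with an estimated correlation. At 24 h 0 rose and 2 fell (0 and 2 adjusted over the list alone). The tissue separation median was -0.91, with adjusted p = 0.388 by camera and adjusted p = 0.693 with an estimated correlation.

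Camera called the suberin, suberin MYB and Casparian strip lists of CASP1::shy2-2/slr-1 down at 24 h but not at 2 h, and these calls were lost with an estimated correlation. Of the suberin genes, 2 of the 14 measured members rose and 1 fell (2 and 1 adjusted over the list alone) at 2 h. The suberin median was 0.09, with adjusted p = 0.711 by camera and adjusted p = 0.883 with an estimated correlation. At 24 h 0 rose and 8 fell (0 and 9 adjusted over the list alone). The suberin median was -0.79, with adjusted p = 0.000695 by camera and adjusted p = 0.26 with an estimated correlation. ASFT fell by 1.55 ± 0.20, ABCG6 by 1.28 ± 0.27 and GPAT5 by 0.89 ± 0.18. Of the suberin MYB factors, 2 of the 7 measured members rose and 0 fell (2 and 0 adjusted over the list alone) at 2 h. The suberin MYB median was 0.10, with adjusted p = 0.238 by camera and adjusted p = 0.647 with an estimated correlation. At 24 h 1 rose and 5 fell (1 and 5 adjusted over the list alone). The suberin MYB median was -0.87, with adjusted p = 0.0148 by camera and adjusted p = 0.408 with an estimated correlation. MYB53 stood at -1.74 ± 0.18. Of the Casparian strip genes, 1 of the 14 measured members rose and 1 fell (1 and 1 adjusted over the list alone) at 2 h. The Casparian strip median was -0.32, with adjusted p = 0.238 by camera and adjusted p = 0.647 with an estimated correlation. At 24 h 1 rose and 11 fell (1 and 12 adjusted over the list alone). The Casparian strip median was -2.53, with adjusted p = 0.000338 by camera and adjusted p = 0.207 with an estimated correlation. ESB1 fell by 3.03 ± 0.32 and the peptide gene CIF1 rose by 1.04 ± 0.17. Of the xylem markers, 0 of the 8 measured members rose and 8 fell (0 and 8 adjusted over the list alone) at 24 h. The xylem median was -2.93, with adjusted p = 2.57e-12 by camera and adjusted p = 0.00631 with an estimated correlation. XCP1 stood at -3.10 ± 0.15 and IRX5 at -3.14 ± 0.16. Of the phenylpropanoid and lignin genes, 6 of the 18 measured members rose and 0 fell (6 and 0 adjusted over the list alone) at 2 h. The phenylpropanoid median was 0.30, with adjusted p = 0.00516 by camera and adjusted p = 0.567 with an estimated correlation. This call was lost with the suffix as a term. At 24 h 1 rose and 11 fell (1 and 11 adjusted over the list alone). The phenylpropanoid median was -0.61, with adjusted p = 1.7e-06 by camera and adjusted p = 0.159 with an estimated correlation. LAC17 fell by 3.71 ± 0.14. Of the GDSL family, 8 of the 54 measured members rose and 12 fell (8 and 12 adjusted over the list alone) at 2 h (adjusted p = 0.406 by camera, adjusted p = 0.647 with an estimated correlation; median -0.06, mean 0.16), and 4 rose and 23 fell (8 and 23 adjusted over the list alone) at 24 h. The GDSL median was -0.44, with adjusted p = 0.0148 by camera and adjusted p = 0.144 with an estimated correlation.

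Of the ethylene genes, 10 of the 16 measured members rose and 1 fell (11 and 1 adjusted over the list alone) at 2 h. The ethylene median was 0.76, with adjusted p = 0.00179 by camera and adjusted p = 0.0518 with an estimated correlation. At 24 h 8 rose and 4 fell (8 and 4 adjusted over the list alone). The ethylene median was 0.73, with adjusted p = 0.0315 by camera and adjusted p = 0.144 with an estimated correlation. The call at 24 h was lost with total count scaling and with libraries without a suffix alone. Of the cell cycle genes, 0 of the 33 measured members rose and 13 fell (0 and 20 adjusted over the list alone) at 2 h. The cell cycle median was -0.32, with adjusted p = 2.96e-05 by camera and adjusted p = 0.567 with an estimated correlation. At 24 h 0 rose and 18 fell (0 and 18 adjusted over the list alone). The cell cycle median was -0.47, with adjusted p = 8.38e-05 by camera and adjusted p = 0.485 with an estimated correlation. AUR2, a mitotic kinase gene, stood at -1.09 ± 0.16. Of the cytokinin genes, 4 of the 17 measured members rose and 4 fell (4 and 5 adjusted over the list alone) at 2 h (adjusted p = 0.835 by camera, adjusted p = 0.905 with an estimated correlation) and 3 rose and 11 fell (3 and 12 adjusted over the list alone) at 24 h. The cytokinin median was -1.16, with adjusted p = 0.00247 by camera and adjusted p = 0.207 with an estimated correlation. The response regulator gene ARR16 stood at -3.16 ± 0.27 and CKX1 at 3.27 ± 0.19. Of the expansins and xyloglucan enzymes, 1 of the 22 measured members rose and 8 fell (1 and 9 adjusted over the list alone) at 2 h. The expansin median was -0.94, with adjusted p = 0.026 by camera and adjusted p = 0.626 with an estimated correlation. This call was lost with the suffix as a term and with total count scaling. EXPB3 stood at -1.73 ± 0.24 and EXPA15 at -1.87 ± 0.33.

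The same test called 6508, 4715, 3130, 6225 and 8925 genes in CASP1::shy2-2/slr-1 at 2, 4, 8, 16 and 24 h, and 15293 over the 5 times. The genes that rose and fell numbered 3289 and 3219 at 2 h, 2222 and 2493 at 4 h, 1632 and 1498 at 8 h, 3308 and 2917 at 16 h, and 4515 and 4410 at 24 h. Scaled by total counts, the share that rose was 36.6% in place of 50.5% at 2 h and 36.8% in place of 47.1% at 4 h. Libraries without a suffix alone gave 9601 and 10812 genes at 16 and 24 h. Only the groups compared gave 2769 at 2 h and 2394 at 16 h. The count depended on single libraries. It was 2985 at 4 h without replicate 2 of that group and 4071 at 16 h without replicate 1 of that group, and at 8 h it was 1842 without control replicate 1 and 1876 without control replicate 3.

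The interaction asks for which transcripts the NAA response itself differed between the genotypes. Camera called the suberin list for a smaller response in CASP1::shy2-2/slr-1 at 2, 4 and 8 h, and the calls were lost with an estimated correlation (adjusted p = 0.0799, 0.0504 and 0.168). GPAT5 rose by 1.41 ± 0.19 in slr-1 at 2 h. Its response in CASP1::shy2-2/slr-1 was lower by -1.26 ± 0.26 at 2 h. At 24 h, when GPAT5 fell in both genotypes, the response was more positive by 3.15 ± 0.28, a smaller fall (adjusted p = 0.00277 and 6.2e-09 for the interaction). MYB53 fell by 6.15 ± 0.31 in slr-1 and by 1.74 ± 0.18 in CASP1::shy2-2/slr-1 at 24 h, a difference of 4.41 ± 0.39 (adjusted p = 4.37e-09). LBD18, a factor of lateral root initiation, responded less in CASP1::shy2-2/slr-1 by -2.67 ± 0.20 at 8 h, while LBD16 responded more at 16 h by 1.60 ± 0.24 (adjusted p at most 7.54e-05).

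The 20 genes with the smallest p in the interaction over the 5 times fell into 2 kinds by direction. One kind fell in slr-1 at 24 h and fell less, rose or stood near its control level in CASP1::shy2-2/slr-1. It held PLP8, a patatin-like protein (-4.19 in slr-1 and -0.57 in CASP1::shy2-2/slr-1, log2), the lipid-transfer protein EDA4 (-4.01 and -1.0), AT5G12420, annotated as a wax ester synthase-like acyltransferase (-3.11 and -0.46), and AT1G56320 (-2.83 and -0.29). It also held MYB53, AT1G78990 (-7.82 and -0.80), AT1G14160, a member of the membrane protein family of CASP1 (-5.02 and -1.05), the cytochrome P450 gene CYP87A2 (-4.59 and -1.37) and GPAT5. The others were AT2G43670 (-2.03 and -0.19), the acyl-CoA synthetase gene LACS2 (-3.91 and -0.76), AT3G52790 (-4.67 and -0.74), AT4G38080 (-3.88 and -0.71) and the dirigent-like gene AT2G21100 (-4.08 and 1.1). The differences of these 14 genes at 24 h lay between 1.84 ± 0.17 for AT2G43670 and 7.02 ± 0.51 for AT1G78990 (adjusted p at most 1.38e-08). The other kind rose in slr-1 without a rise at that time in CASP1::shy2-2/slr-1. It held the strictosidine synthase-like gene SSL2, with a difference of -5.58 ± 0.30, AT2G36670, annotated as an aspartyl protease (-2.15 ± 0.14), and the VQ motif gene AT5G08480 (-4.48 ± 0.29) at 24 h. AT1G19200 (-3.15 ± 0.21) and the early nodulin-like gene ENODL16 (-2.77 ± 0.19) belonged to it at 16 h and the receptor kinase gene AT3G24240 (-3.09 ± 0.27) at 4 h. SAG29, which rose in slr-1 at 24 h, had a difference of -5.0 ± 0.61 there (adjusted p = 1.66e-06).

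**Figure D4:**
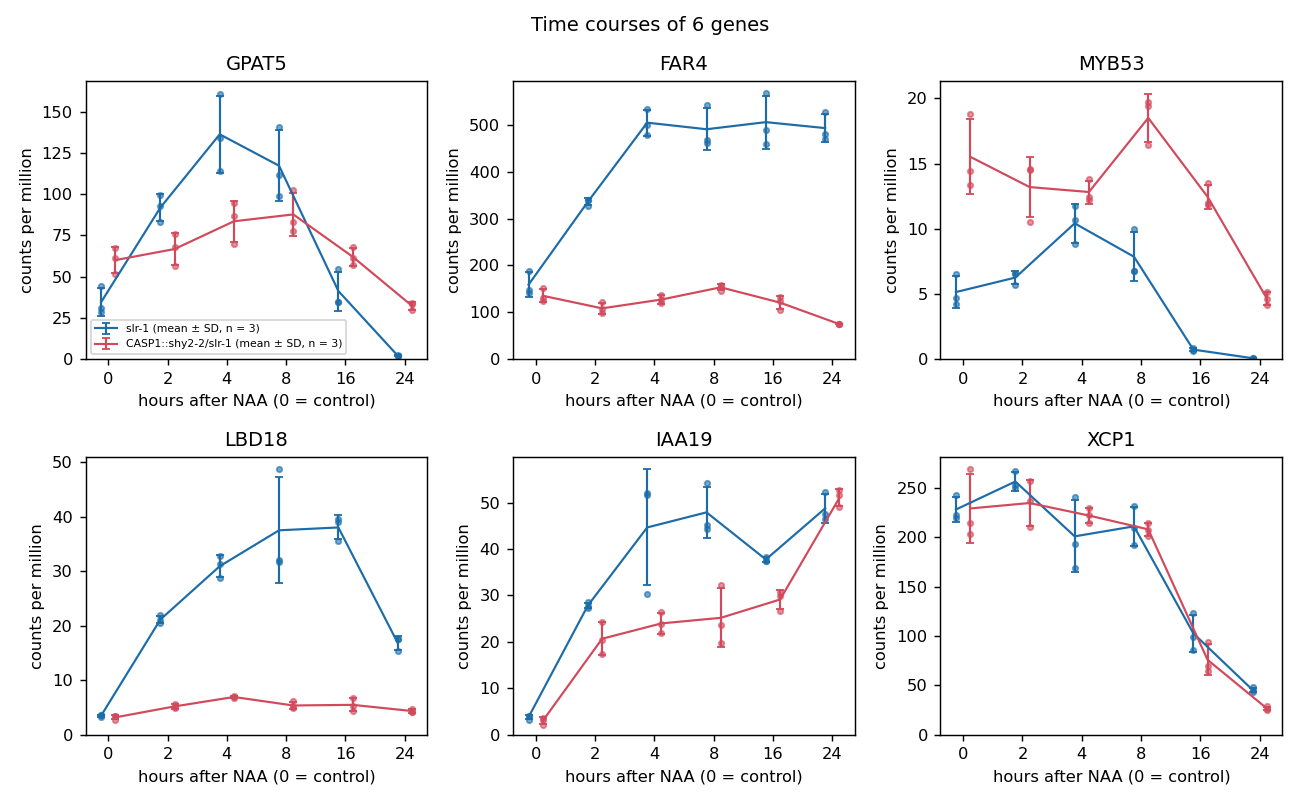
CPM of GPAT5, FAR4, MYB53, LBD18, IAA19 and XCP1 in each library of both genotypes against hours of NAA. Means ± SD are of the 3 libraries per group. LBD18 responded less in CASP1::shy2-2/slr-1 at 8 h. At 24 h FAR4 rose in slr-1 and fell in the other genotype, and IAA19 rose in both.

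The interaction called 14 of the 14 measured suberin genes over the 5 times (14 adjusted over the list alone). At 2 h 0 responded more and 11 less in CASP1::shy2-2/slr-1 (0 and 11 adjusted over the list alone) . The median difference was -1.33, with adjusted p = 1.23e-09 by camera and adjusted p = 0.0799 with an estimated correlation. At 4 h 0 responded more and 12 less in CASP1::shy2-2/slr-1 (0 and 12 adjusted over the list alone). The median difference was -1.30, with adjusted p = 4.99e-12 by camera and adjusted p = 0.0504 with an estimated correlation. At 8 h 0 responded more and 9 less in CASP1::shy2-2/slr-1 (0 and 9 adjusted over the list alone). The median difference was -1.23, with adjusted p = 7.15e-09 by camera and adjusted p = 0.168 with an estimated correlation. At 24 h the response was more positive in CASP1::shy2-2/slr-1 for 6 and more negative for 4 (7 and 4 adjusted over the list alone). The list's median fell less there, at -0.79 against -1.4 in slr-1. The median difference was 0.57, with adjusted p = 0.385 by camera and adjusted p = 1 with an estimated correlation. With libraries without a suffix alone, of which 1 is CASP1::shy2-2/slr-1 at 8 h, the suberin median at 8 h was -1.13. At 24 h CYP86A1 (4.77 ± 0.38) and CYP86B1 (2.79 ± 0.34) had a more positive response in CASP1::shy2-2/slr-1 than in slr-1, and FAR4 differed the other way by -2.49 ± 0.15. Of the suberin MYB factors, 7 of 7 were called over the 5 times (7 over the list alone), with a median of -1.25 at 4 h (adjusted p = 0.000582 by camera, adjusted p = 0.243 with an estimated correlation) and 1.68 at 24 h (adjusted p = 8.65e-05 by camera, adjusted p = 0.329 with an estimated correlation). MYB39 differed by 4.20 ± 0.61 and MYB9 by 1.68 ± 0.38 at 24 h. Of the Casparian strip genes 4 of 14 were called over the 5 times (6 over the list alone), among them SGN3 (1.47 ± 0.29) and CIF1 (0.88 ± 0.23) at 24 h, where the list's median was -0.05 and its mean 0.28 (adjusted p = 0.867 by camera, adjusted p = 1 with an estimated correlation). Of the xylem markers 6 of 8 were called (6 over the list alone), with medians of -1.03 at 16 h (adjusted p = 0.000285 by camera, adjusted p = 0.358 with an estimated correlation) and -0.94 at 24 h (adjusted p = 7.42e-05 by camera, adjusted p = 0.318 with an estimated correlation), among them IRX5 (-1.27 ± 0.21) and IRX1 (-1.14 ± 0.23). Of the phenylpropanoid genes 9 of 18 were called (10 over the list alone), among them LAC17 (-1.33 ± 0.17) and PAL4 (-1.60 ± 0.23). Of the GDSL family 24 of 54 were called (28 over the list alone), among them AT1G74460 (2.77 ± 0.29) and AT2G23540 (3.77 ± 0.34).

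Among the auxin lists, 14 of 27 Aux/IAA repressors were called over the 5 times (15 over the list alone), with a median of -0.25 at 2 h (adjusted p = 0.0486 by camera, adjusted p = 0.65 with an estimated correlation), a call lost with the suffix as a term and with total count scaling. The response of IAA9 was more positive in CASP1::shy2-2/slr-1 at 24 h (0.73 ± 0.11), and IAA29 responded less there at 8 h (-1.95 ± 0.34). Of the conjugation genes 6 of 10 were called (8 over the list alone), with a median of -0.64 at 2 h (adjusted p = 7.15e-05 by camera, adjusted p = 0.0799 with an estimated correlation), GH3.3 at -2.76 ± 0.31 at 2 h and GH3.2 at -2.65 ± 0.23 at 24 h. At 24 h the median of this list was 0.05 and its mean -0.34 (adjusted p = 0.204 by camera, adjusted p = 0.869 with an estimated correlation). Of the receptors and ARFs 8 of 17 were called (9 over the list alone), with a median of -0.44 at 2 h (adjusted p = 0.000404 by camera, adjusted p = 0.147 with an estimated correlation) and ARF4 at -1.34 ± 0.20, ARF16 at -1.08 ± 0.13 and ARF19 at -1.04 ± 0.17. Of the transport genes 13 of 19 were called (15 over the list alone), with medians of -0.66, -0.64 and -0.63 at 2, 4 and 8 h (adjusted p = 7.15e-05, 0.000563 and 0.000296 with camera, adjusted p = 0.147, 0.243 and 0.212 with an estimated correlation). AUX1, the influx carrier gene, differed by -0.66 ± 0.14 at 2 h and PIN3 and PIN7, efflux carrier genes, by 1.01 ± 0.23 and 1.08 ± 0.26 at 24 h. Of the lateral root genes 12 of 16 were called (12 over the list alone), with a median of -0.78 at 2 h (adjusted p = 0.0162 by camera, adjusted p = 0.5 with an estimated correlation) and MAKR4 at 3.12 ± 0.45 at 24 h. Of the tissue separation genes 3 of 9 were called (4 over the list alone), with a median of -0.92 at 2 h, or -0.81 with a member at 0 reads set at 3 counts over its group (adjusted p = 0.0652 by camera, adjusted p = 0.5 with an estimated correlation), and HSL2 at -1.54 ± 0.23 and LAX3, an auxin influx carrier gene, at -1.44 ± 0.30 at 4 h.

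Among the other lists, 6 of 33 cell cycle genes (4 over the list alone), 5 of 22 expansins and xyloglucan enzymes (5), 6 of 16 ethylene genes (6) and 7 of 17 cytokinin genes (10) were called by the interaction over the 5 times. CKX4 differed by 4.08 ± 0.32 and ACS7 by -2.15 ± 0.38 at 24 h, CKX5 by -2.13 ± 0.20 at 16 h, EBF1 by -0.65 ± 0.13 at 2 h and HIK, a kinesin gene of cytokinesis, by -0.86 ± 0.20 at 16 h (adjusted p at most 0.00589).

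The interaction called 3258, 2501, 2433, 1976 and 2897 genes at 2, 4, 8, 16 and 24 h and 5534 over the 5 times. Genes with a more positive and a more negative response in CASP1::shy2-2/slr-1 numbered 1777 and 1481 at 2 h, 1238 and 1263 at 4 h, 1180 and 1253 at 8 h, 946 and 1030 at 16 h, and 1503 and 1394 at 24 h. Scaled by total counts, the share with a more positive response was 34.7% in place of 48.5% at 8 h, 36.2% in place of 47.9% at 16 h and 36.8% in place of 51.9% at 24 h. Libraries without a suffix alone gave 2588 and 5406 genes at 16 and 24 h. At 2 and 16 h the suffix as a term gave 6308 and 3312, and only the groups compared gave 1077 and 790. Leaving out the suffix x library alone gave 5846 at 2 h. The counts at single times depended on single libraries. At 2 h the count was 1482 without slr-1 control replicate 1, 1987 and 2078 without slr-1 2 h replicates 1 and 2, 1961 without CASP1::shy2-2/slr-1 control replicate 3, and 5846 and 1184 without CASP1::shy2-2/slr-1 2 h replicates 2 and 3. At 4 h it was 919, 1297 and 4361 without slr-1 control replicates 1, 2 and 3, 1208 and 1288 without slr-1 4 h replicates 1 and 2, 1482 without CASP1::shy2-2/slr-1 control replicate 3, and 1447 and 1016 without CASP1::shy2-2/slr-1 4 h replicates 2 and 3. At 8 h it was 1097 without slr-1 control replicate 1, 1600 without slr-1 8 h replicate 1, 1605 and 1340 without CASP1::shy2-2/slr-1 control replicates 1 and 3, and 1174 without CASP1::shy2-2/slr-1 8 h replicate 1. At 16 h it was 1034 without slr-1 control replicate 1, 1309 without slr-1 16 h replicate 2, 1152 without CASP1::shy2-2/slr-1 control replicate 3 and 1280 without CASP1::shy2-2/slr-1 16 h replicate 3, and at 24 h 1906 and 1917 without slr-1 control replicate 1 and CASP1::shy2-2/slr-1 control replicate 3. Without slr-1 control replicate 3 and CASP1::shy2-2/slr-1 8 h replicate 3 together it was 4409 at 4 h and 2976 at 16 h.

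Untreated roots of the genotypes were compared to see how they differ without NAA. Other differences between the plants of the 2 genotypes are not separated from an effect of shy2-2. UMAMIT25, a transporter gene, was lower in CASP1::shy2-2/slr-1 (-6.68 ± 0.30), as were MRD1 (-6.38 ± 0.43), AT5G15360 (-6.11 ± 0.35) and the prenyltransferase gene cPT5 (-4.28 ± 0.27), and RTFL10 stood at 2.34 ± 0.363 CPM in slr-1 and 0.0538 ± 0.00650 CPM in CASP1::shy2-2/slr-1. AT5G04120 (6.33 ± 0.51), the peroxidase gene AT5G19890 (5.61 ± 0.68), the MADS-box gene AP3 (3.49 ± 0.31), the nitrate reductase gene NIA1 (3.39 ± 0.87) and ATSDI1, a sulfur deficiency-induced gene (3.26 ± 0.53), were higher (adjusted p at most 0.00592 for the 10 genes). Of the Aux/IAA repressors none was higher and 7 were lower (0 and 10 adjusted over the list alone), with a median difference of -0.24 (adjusted p = 0.0364 by camera, adjusted p = 0.59 with an estimated correlation). Conjugation genes (0.40, adjusted p = 0.0276 by camera, adjusted p = 0.59 with an estimated correlation), receptors and ARFs (0.22, adjusted p = 0.0276 by camera, adjusted p = 0.59 with an estimated correlation) and cytokinin genes (0.40, adjusted p = 0.0256 by camera, adjusted p = 0.59 with an estimated correlation) were called higher. Of the suberin genes 5 of 14 were higher and none was lower (5 and 0 adjusted over the list alone), with a median of 0.10 (adjusted p = 0.222 by camera, adjusted p = 0.725 with an estimated correlation), and MYB53 was higher by 1.59 ± 0.17.

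The test called 5223 genes between the untreated genotypes, 2572 higher and 2651 lower in CASP1::shy2-2/slr-1, and 7754 in a model of the libraries without a suffix, which include every control. Scaled by total counts, the share that was higher was 59.4% in place of 49.2%. The count was 2915 with only the groups compared, 2537 without slr-1 control replicate 1 and 3175 without CASP1::shy2-2/slr-1 control replicate 3.

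Responses of the genotypes were then set side by side. Genes that rose in slr-1 at 2 h had a median log2 fold change of 0.65 there and of 0.26 in CASP1::shy2-2/slr-1, and at 24 h of 0.57 and 0.30. Genes that fell in slr-1 had medians of -0.51 and -0.21 at 2 h and of -0.67 and -0.41 at 24 h. Taken the other way, genes that rose in CASP1::shy2-2/slr-1 at 2 h had medians of 0.61 there and 0.36 in slr-1, so that part of each contrast follows from selecting genes in one genotype. At 2, 4, 8, 16 and 24 h, 1741, 1388, 854, 2028 and 2330 genes rose in both genotypes, against 666, 451, 293, 741 and 1054 for independent lists, and 186, 127, 116, 218 and 316 moved in opposite directions, against 1394, 990, 560, 1397 and 2241. Across the 20939 genes, which are not independent replicates, Pearson's r of the fold changes was 0.46, 0.51, 0.53, 0.63 and 0.65 and Spearman's rho 0.46, 0.42, 0.39, 0.57 and 0.63. The comparisons of the genotypes share no libraries. IAA19, ACS8 and AHP4 were among the genes that rose in both at 24 h, and CASP1, ESB1 and XCP1 among those that fell in both. All p-values measure the spread between these libraries, since the labels do not say whether the 3 of a group came from separate cultures.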

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

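Tests chosen after the result was seen were those of the suffix as a term for the suberin genes, of the starting level, of a weaker treatment, of a lower share of endodermal cells and of transgene reads, and the bound of 0.001 for the adjusted p of a list.

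The response to NAA differed between the genotypes for 3258, 2501, 2433, 1976 and 2897 genes at 2, 4, 8, 16 and 24 h and for 5534 over the 5 times. Genotype labels were exchanged within each time in other splits of the same libraries. With the real grouping counted as 1 split, 2 of 21, 3 of 21, 1 of 21, 4 of 21 and 1 of 21 splits reached the real count at 2, 4, 8, 16 and 24 h. Over the 5 times 1 of 25 did, again with the real grouping counted. The highest other splits called 3316, 2678, 2285, 3968, 1840 and 2047 genes. Those 6 splits exchanged unequal numbers of libraries at different times, which carries the genotype difference without NAA into the interaction. With equal numbers at both times the highest counts were 0, 0, 0, 615 and 0, in splits that mix the genotypes within groups. Neither kind shows what chance gives without an interaction, so these splits leave open whether chance can be excluded.

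The 20 genes with the smallest interaction p differed in response by these log2 values at 24 h: PLP8 3.62, EDA4 3.01, AT2G36670 -2.15, SSL2 -5.58, AT5G12420 2.65, AT1G56320 2.54, MYB53 4.41, AT1G78990 7.02, AT1G14160 3.97, CYP87A2 3.22, GPAT5 3.15, AT2G43670 1.84, AT5G08480 -4.48, LACS2 3.15, AT2G21100 5.18, AT3G52790 3.93 and AT4G38080 3.2. At 16 h the values were -3.15 for AT1G19200 and -2.77 for ENODL16, and at 4 h -3.09 for AT3G24240.

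Lists that differed in response were auxin conjugation at 2 h (median -0.64), receptors and ARFs at 2 h (-0.44), auxin transport at 2, 4 and 8 h (-0.66, -0.64 and -0.63), suberin at 2, 4 and 8 h (-1.33, -1.30 and -1.23), suberin MYB factors at 4 h (-1.25) and 24 h (1.68), and xylem markers at 16 h (-1.03) and 24 h (-0.94). With an estimated correlation none of these 12 list differences passed the test, with adjusted p of 0.0504 to 0.358.

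Of the 14 suberin genes 11, 12 and 9 responded less in CASP1::shy2-2/slr-1 at 2, 4 and 8 h, and the list's calls were lost with an estimated correlation (adjusted p = 0.0799, 0.0504 and 0.168). In libraries without a suffix the medians at 4 and 8 h were -1.19 and -1.13. These exclude nothing, since 1 CASP1::shy2-2/slr-1 library is left at each time. An additive effect of the suffix would need the difference to vanish with the suffix as a term, and the medians were then -1.37, -1.26 and -1.23 at 2, 4 and 8 h (standard error 0.18 at 8 h). A suffix effect that differs between the genotypes was not tested, and at 2 h every library has a suffix. A higher starting level would need the controls to differ, and their median difference was 0.10 (0.13). For the 5 of 14 members that were higher in the CASP1::shy2-2/slr-1 controls, such as GPAT5 (0.80 ± 0.18), a higher starting level stays open. A weaker treatment of all auxin-responsive genes cannot be told apart. The suberin median lay -1.08 (0.23) from the Aux/IAA median at 2 h, but the Aux/IAA list rose by 0.82 in slr-1 and had less to lose, and the conjugation, transport and lateral root medians were also negative (-0.64, -0.66 and -0.78), with calls lost with an estimated correlation. Root tip markers, with few reads and 0 of 7 called, gave medians of -3.54 at 2 h (-1.01 with members at 0 reads set at 3 counts) and -1.81 at 4 h, and a difference between the root sections was not tested. The genotype difference that the design names, shy2-2 in the endodermis, stays open and was not tested.

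Of the 14 Casparian strip genes 11 fell in each genotype at 24 h and 1 rose in CASP1::shy2-2/slr-1, and the list's calls were lost with an estimated correlation (adjusted p = 0.283 and 0.207). A lower share of endodermal cells would raise the markers of other cell types alike. Xylem markers stood at -1.87 (0.13) in slr-1 and at -2.93 (0.13) in CASP1::shy2-2/slr-1, phloem markers at -0.58 and -0.40, root hair markers at -1.67 and -2.27, and root tip markers at 2.32 and 0.37. The xylem list alone was called by camera (root tip adjusted p = 0.072 and 0.521). Since each cell type can have changes of its own, a lower share of endodermal cells cannot be told apart from less transcript per cell. Scaling by TMM was tested with total counts, which gave a median of -2.66 (0.32). Seedlings were 7 days old in every group. The hours since transfer cannot be told apart from NAA, since the labels do not say how long the untreated seedlings had been on control plates and name 0 untreated libraries at 24 h.

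IAA3 counts rose with NAA in slr-1 and fell in CASP1::shy2-2/slr-1 at 16 h. Transgene reads added to an equal native level would make the second genotype higher, and it differed by -1.49 (0.13) at 8 h. With the suffix as a term the interaction at 16 h was -1.99 (0.18). Whether the native gene or the transgene responded was not tested, since the counts do not separate them.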

How the results depend on the processing

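Total count scaling and leaving out 2 libraries together were chosen after seeing the data. With RLE factors, DESeq2, the replicate block, no filter and total count scaling, calls stayed within 1.5 times the main count in all 19 comparisons. With the replicate block it was 8932 in slr-1 at 2 h and 3166 in the interaction at 2 h, and the ARF list of slr-1 at 16 h lost its call. Of 158 list calls, 33 were kept and 125 lost with an estimated correlation. Total count scaling kept 146 list calls and weakened 12. Changes of 1.5-fold were recovered in 10.4% of simulated cases in the interaction at 2 h, and recovery by read level was not tested.

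Counts outside 1.5 times the main count follow, and the cause was not tested beyond the stricter threshold or fewer libraries. With a log2 fold change of at least 1, slr-1 gave 2112, 2391, 1977, 2503 and 3169 genes and 5320 over the times, CASP1::shy2-2/slr-1 1429, 1193, 935, 1711 and 2289 and 4252, the interaction 1047, 994, 847, 847 and 1037 and 2163, and the untreated genotypes 1096. With an adjusted p under 0.01, slr-1 gave 5829, 4609 and 6153 at 4, 8 and 16 h, CASP1::shy2-2/slr-1 4013, 2529, 1626 and 3569 at 2, 4, 8 and 16 h, the interaction 993, 613, 710, 721 and 1372 and 2608, and the untreated genotypes 2585. With only the groups compared, slr-1 at 16 h gave 5242, CASP1::shy2-2/slr-1 2769 at 2 h and 2394 at 16 h, the interaction 1077 at 2 h and 790 at 16 h, and the untreated genotypes 2915. Libraries without a suffix gave 9601 in CASP1::shy2-2/slr-1 at 16 h and 5406 in the interaction at 24 h. No control or 24 h library has a suffix, so 24 h changes, those of lists too, come from the other libraries in the fit. The suffix as a term gave 6308 and 3312 in the interaction at 2 and 16 h, and leaving out slr-1 control replicate 3 and CASP1::shy2-2/slr-1 8 h replicate 3 gave 4409 at 4 h and 2976 at 16 h.

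With 1 library left out, counts ran from 4878 to 8189 in slr-1 at 8 h, 2985 to 4484, 1842 to 3496 and 4071 to 7869 in CASP1::shy2-2/slr-1 at 4, 8 and 16 h, 1184 to 5846, 919 to 4361, 1097 to 3243, 1034 to 2921 and 1906 to 2886 in the interaction, and 2537 to 5633 between the untreated genotypes. 4 interaction values reversed, and the cause was not tested. At 8 h, libraries without a suffix gave -3.78 for LRX1, -1.41 for RSL4 and -0.72 for CASP1, values that rest on 1 CASP1::shy2-2/slr-1 library at 8 h (replicate 3), assumed to vary like the other groups. For LRX1, log2 fold change, genotype by NAA interaction at 8 h, the values ran from -0.26 (without slr-1 control replicate 3) to 7.055 (without slr-1 8 h replicate 1). IAA14 ran at 24 h from -0.30 (without CASP1::shy2-2/slr-1 24 h replicate 1) to 0.13 (without CASP1::shy2-2/slr-1 control replicate 2).

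In other splits of the 6 libraries, which are too few for a share under 0.05, the highest other counts in slr-1 were 0, 0, 1, 5300 and 0 at 2, 4, 8, 16 and 24 h, against 8964, 8807, 7487, 9398 and 10506. The 5300 came from exchanging replicate 3 of the controls and of the 16 h group. In CASP1::shy2-2/slr-1 they were 264, 1, 715, 2 and 0, against 6508, 4715, 3130, 6225 and 8925, and between the untreated genotypes 23 against 5223. In each case 1 of 10 splits, the real one, reached the real count. Over the 5 times 1 of 25 splits, the real one, did, a share under 0.05 and the lowest that 25 splits can give. The highest other counts were 11615 against 17045 in slr-1 and 8913 against 15293 in CASP1::shy2-2/slr-1. The other splits mix times within groups, so this share alone does not exclude chance.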

Other observations

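Camera called the abscisic acid response and detoxification lists up at 2 h in both genotypes, and in CASP1::shy2-2/slr-1 these calls were lost with an estimated correlation. Of the abscisic acid response genes, 9 of the 10 measured members rose and 0 fell (9 and 0 adjusted over the list alone) in slr-1. The abscisic acid median was 2.37, with adjusted p = 2.91e-07 by camera and adjusted p = 0.0232 with an estimated correlation. In CASP1::shy2-2/slr-1 6 rose and 0 fell (6 and 0 adjusted over the list alone). The abscisic acid median was 1.22, with adjusted p = 6.32e-06 by camera and adjusted p = 0.0518 with an estimated correlation. RD29A rose by 3.44 ± 0.24, KIN1 by 2.65 ± 0.21 and the phosphatase gene ABI1 by 0.99 ± 0.13 in slr-1. Of the detoxification genes, 11 of the 11 measured members rose and 0 fell (11 and 0 adjusted over the list alone) in slr-1. The detoxification median was 1.87, with adjusted p = 3.15e-10 by camera and adjusted p = 0.0399 with an estimated correlation. In CASP1::shy2-2/slr-1 10 rose and 0 fell (11 and 0 adjusted over the list alone). The detoxification median was 1.35, with adjusted p = 4.88e-09 by camera and adjusted p = 0.061 with an estimated correlation. GSTU19 and GSTF8, glutathione transferase genes, rose by 1.62 ± 0.14 and 1.82 ± 0.23 and OPR1 by 2.17 ± 0.23 in slr-1 at 4 h. Of the jasmonate and wounding genes, 4 of the 8 measured members rose and 0 fell (4 and 0 adjusted over the list alone) in slr-1. The jasmonate median was 1.12, with adjusted p = 0.0323 by camera and adjusted p = 0.483 with an estimated correlation. In CASP1::shy2-2/slr-1 4 rose and 0 fell (4 and 0 adjusted over the list alone) (adjusted p = 0.116 by camera, adjusted p = 0.647 with an estimated correlation). JAZ1 and JAZ5, jasmonate repressor genes, rose by 1.86 ± 0.22 and 1.45 ± 0.36 in slr-1. The interaction over the times called 3 of 10 abscisic acid, 3 of 11 detoxification and 4 of 8 jasmonate genes (3, 3 and 4 adjusted over the list alone). The response of VSP2, a wound-induced gene, differed by -3.34 ± 0.74 at 24 h.

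Of the circadian clock genes, 7 of the 11 measured members rose and 1 fell (7 and 1 adjusted over the list alone) in slr-1 at 2 h. The clock median was 0.79, with adjusted p = 0.0178 by camera and adjusted p = 0.483 with an estimated correlation. This call was lost with the suffix as a term. LHY rose by 1.02 ± 0.13 and ELF3 by 0.79 ± 0.13. In CASP1::shy2-2/slr-1 3 rose and 0 fell (3 and 0 adjusted over the list alone) (adjusted p = 0.0867 by camera, adjusted p = 0.626 with an estimated correlation). Of the iron uptake genes, 2 of the 7 measured members rose and 0 fell (2 and 0 adjusted over the list alone) in slr-1 (adjusted p = 0.583 by camera, adjusted p = 0.924 with an estimated correlation) and 3 rose and 0 fell (3 and 0 adjusted over the list alone) in CASP1::shy2-2/slr-1 (adjusted p = 0.0867 by camera, adjusted p = 0.626 with an estimated correlation) at 2 h. BHLH39 and BHLH38, regulators of iron uptake, rose by 2.41 ± 0.30 and 2.35 ± 0.40 in slr-1 at 8 h. The interaction over the times called 4 of 11 clock genes and 1 of 7 iron genes (4 and 1 adjusted over the list alone).

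The lists of root hair, phloem, pericycle, root tip and shoot markers were not called by camera at 24 h in either genotype. Of the root hair and epidermis markers, 1 of the 10 measured members rose and 4 fell (1 and 4 adjusted over the list alone) in slr-1 at 24 h. The root hair median was -1.67, with adjusted p = 0.481 by camera and adjusted p = 0.85 with an estimated correlation. In CASP1::shy2-2/slr-1 1 rose and 4 fell (1 and 5 adjusted over the list alone) (adjusted p = 0.168 by camera, adjusted p = 0.69 with an estimated correlation) at 24 h. Of the phloem markers, 0 of the 6 measured members rose and 3 fell (0 and 4 adjusted over the list alone) in slr-1 (adjusted p = 0.245 by camera, adjusted p = 0.444 with an estimated correlation) and 1 rose and 4 fell (1 and 4 adjusted over the list alone) in CASP1::shy2-2/slr-1 (adjusted p = 0.209 by camera, adjusted p = 0.457 with an estimated correlation) at 24 h, with SUC2, a sucrose carrier gene, at -1.09 ± 0.23 in slr-1 at 4 h. Of the root tip and cap markers, 3 of the 7 measured members rose and 0 fell (4 and 0 adjusted over the list alone) in slr-1 (adjusted p = 0.072 by camera, adjusted p = 0.512 with an estimated correlation) and 1 rose and 0 fell (1 and 0 adjusted over the list alone) in CASP1::shy2-2/slr-1 (adjusted p = 0.521 by camera, adjusted p = 0.832 with an estimated correlation) at 24 h, and WOX5 stood at 0.599 ± 0.159 CPM in the slr-1 controls and 1.65 ± 0.371 CPM at 24 h. Of the shoot and photosynthesis markers, 0 of the 8 measured members rose and 4 fell (0 and 4 adjusted over the list alone) in slr-1 at 2 h. The shoot median was -0.89, with adjusted p = 0.152 by camera and adjusted p = 0.614 with an estimated correlation. The pericycle and stele list held PHO1 and SKOR, and both had a more positive response in CASP1::shy2-2/slr-1 at 2 h. The pericycle median difference was 1.17, with adjusted p = 0.0417 by camera and adjusted p = 0.269 with an estimated correlation. At 4 h the list's median change was -1.25 in slr-1 and -0.01 in CASP1::shy2-2/slr-1. The response of PHO1 differed by 0.81 ± 0.17 at 16 h. The cortex list held 1 gene, PEP_AT1G09750, which fell in CASP1::shy2-2/slr-1 at 4 h (-3.36 ± 1.04), rose in both genotypes at 16 h (2.90 ± 0.83 in slr-1 and 2.35 ± 0.69) and was called at no single time in the interaction. The interaction over the times called 0 of 10 root hair, 3 of 6 phloem, 2 of 2 pericycle, 1 of 7 root tip, 0 of 8 shoot and 0 of 1 cortex markers (0, 3, 2, 1, 0 and 0 adjusted over the list alone).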
